A study of Mus musculus with 12 samples.

How the data were processed

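Gene expression was measured on Affymetrix mouse arrays in 12 samples of cultured type II alveolar epithelial cells, the surfactant-producing cells of the lung alveolus. The samples fall into 4 genotype groups of 3 arrays each: Gna11 knockout, Gnaq/Gna11 double knockout, Gna12 knockout and Gna12/Gna13 double knockout. Per the labels, the cells came from mouse lungs and were kept for 7 days on plates coated with collagen, in a bronchial epithelial medium with keratinocyte growth factor and no hydrocortisone, renewed every 3 days. RNA was taken up in Trizol, and 10 ng of total RNA per sample was amplified and labelled with biotin before hybridisation, also per the labels. The labels do not say whether the 3 samples of a group came from separate animals or separate cultures, so every p-value measures only the spread between these samples, which may be technical in part. The Y-linked gene Eif2s3y was low in replicate 2 and high in replicates 1 and 3 of the Gna11, Gna12 and Gna12/Gna13 groups, so the arrays of these groups do not all stem from 1 animal.

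The deposited values are expression summaries per probe set that the authors made with RMA, per the submitters' processing notes, and they are read here as log2 values. RMA corrects the background, normalizes between arrays and summarises the probes of each probe set. The software, its version and the annotation are not given in the sources used here. The base of the logarithm is not stated either. It was taken as 2 because RMA gives log2 values and the values of the arrays run from 2.13 to 14.1, so every fold change rests on that reading. The medians of the 12 arrays lay between 5.031 and 5.11, and the lowest correlation of an array with another of its group was 0.963. No pair of arrays held identical values. The number of arrays limits the precision of every value.

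The table held 45101 probe sets, of which 64 were controls. The platform annotation used here named 1 gene for 34945 probe sets, several genes for 932 and none for 9160. Symbols were updated through the gene number with the RefSeq gene table of assembly GRCm38.p6, which held 34741 of the 34945 probe sets, and the other 204 kept the platform's symbol. The authors' genome build is not given in the sources used here, so no coordinates are printed and the table served only for names and for the order of genes along a chromosome. Each gene was represented by its probe set with the highest mean over the 12 arrays. This gave 18193 genes, and 9010 of them had more than 1 probe set.

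A linear model with 1 mean per group was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 8 residual and 3.19 prior degrees of freedom). The tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 18193 genes of a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were Gnaq/Gna11 minus Gna11, Gna12/Gna13 minus Gna12, the difference between these differences, and Gna12 minus Gna11. A position code in the labels ends in 2 for both groups lacking Gna11 and in 4 for both groups lacking Gna12, and its letter is B, C or D in both single and E, F or G in both double knockouts. The meaning of the code is not given in the sources used here. Its number cannot be told apart from genotype between the single knockouts, nor its letter between a double and its single knockout. The targeted genes were examined in every array and probe set, with an exact two-sided permutation test of the knockout arrays against all other arrays, adjusted over the 21 probe sets. With 3 arrays against 3 the smallest exact p is 0.1.

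Gene lists for cell types, signalling, immune, metabolic and growth genes were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of 565 list entries, 529 were measured, 2 of these through an older symbol, and 36 were not. In total 32 lists with at least 5 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. The p-values of fry test whether the genes of a list move on balance in 1 direction, and those of its mixed form whether they change in either direction. Neither compares a list with other genes. Lists of pan-leukocyte, dendritic, alternatively activated macrophage, and eosinophil and mast cell genes, and the list of xenobiotic and aldehyde metabolism gene families, were added after the data had been examined.

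The genes named for a comparison are the targeted genes, up to 10 with the largest rises and 10 with the largest falls, and up to 4 members of each fixed list. The largest changes were taken among called genes whose 2 groups did not overlap, with a higher group mean at or above 5.101, the median of the non-control probe sets, a probe set assigned to 1 gene, and a symbol other than a clone, predicted or RIKEN name. Where fewer than 10 genes passed, those with the smallest unadjusted p filled the number and are given as values that did not pass. For the difference between the differences, the groups of at least 1 of the pairs had to be free of overlap. List members that passed were taken first, then those with the largest absolute difference. Other genes are named outside this rule, among them members of the added lists, genes called under single alternatives and genes near Gnaq.

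The procedure was tested on simulated arrays built from the mean over the 12 arrays and the residual spread of each of the 18193 genes, with 50 genes changed by each of 4 known amounts. For Gnaq/Gna11 against Gna11, 24% of the genes changed by 0.5 on the log2 scale were called, 60% of those changed by 1, 86% of those changed by 2 and 92% of those changed by 3, and 9.46% of the calls were false. For Gna12/Gna13 against Gna12 the shares were 10%, 54%, 94% and 98%, with 5.19% of the calls false. For the difference between the differences they were 2%, 26%, 72% and 94%, with 4.85% false. For Gna12 against Gna11 they were 18%, 78%, 86% and 100%, with 5.19% false. The genes were simulated independently, so this does not test how often camera calls lists of correlated genes.

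The alternatives were the mean of the probe sets of a gene, every probe set tested on its own, a filter on dim genes, quantile normalization of the deposited values, centring of each array, no intensity trend, array quality weights, only the arrays compared, other thresholds, the replicate number as a block, and each array left out in turn. Added after the data were examined were the level of the Y-linked gene Eif2s3y, the difference between the 3' and 5' Gapdh control probe sets (a measure of RNA integrity and amplification) and the mean of 20 pan-leukocyte genes as covariates, and a fit without the 2 Gna11 arrays with high Eif2s3y. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.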

Results

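RNA from type II alveolar epithelial cells, cultured for 7 days without further treatment, was profiled on 12 arrays. The cells lacked Gna11, Gnaq and Gna11, Gna12, or Gna12 and Gna13, with 3 arrays per genotype. These genes encode the alpha subunits of the heterotrimeric G proteins Gq, G11, G12 and G13, which link cell surface receptors to phospholipase C and calcium (Gq/11) and to RhoA (G12/13). The stated purpose was to compare cells of single and double knockout mice. Each array gave values for 45101 probe sets, with medians between 5.031 and 5.11 on the log2 scale. Values below are group means ± SD on this scale, and differences are log2 differences with the standard error of the limma model, with n = 3 arrays per group.

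The arrays differed in measures other than genotype. The first principal component held 27.7% of the variance and separated the 6 arrays lacking Gna11 from the 6 lacking Gna12. The second held 18.6%, and replicate 2 of the Gna11 cells had the highest score on it, 50.9. The mean of 20 pan-leukocyte genes was 7.73 ± 0.312 in Gna11 cells, 8.47 ± 0.0256 in Gnaq/Gna11 cells, 8.99 ± 0.330 in Gna12 cells and 8.66 ± 0.460 in Gna12/Gna13 cells. The 3' minus 5' difference of the Gapdh control probe sets, which grows as RNA is degraded or shortened, was 3.70 ± 0.295, 3.14 ± 0.125, 3.00 ± 0.298 and 3.15 ± 0.174 in the same order. The same difference for the Actb control probe sets was 3.021 to 3.346 in Gna11 and 2.753 to 3.381 in Gnaq/Gna11 arrays. It was 2.862 to 3.146 in Gna12 and 3.015 to 3.345 in Gna12/Gna13 arrays, so Actb did not set the Gna11 arrays apart. Eif2s3y, a gene of the Y chromosome, was at 3.33 to 3.54 in the 3 Gnaq/Gna11 arrays, while in each other group replicates 1 and 3 lay at 6.91 or above and replicate 2 at 3.56 or below.

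**Figure D1:**
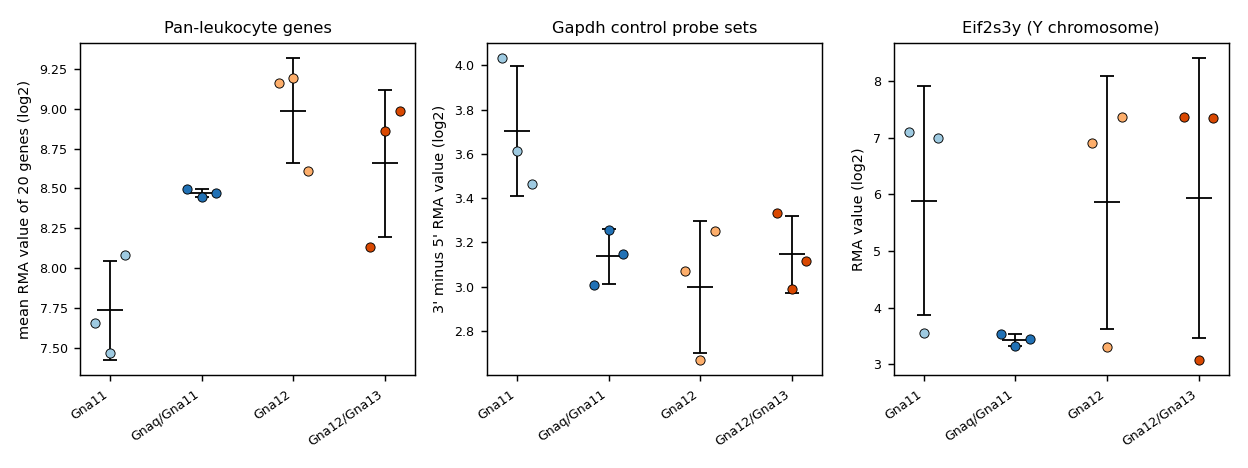
Points are the 12 arrays, and bars give the group mean ± SD (n = 3) on the log2 scale for the mean of 20 pan-leukocyte genes, the 3' minus 5' difference of the Gapdh control probe sets and the Y-linked gene Eif2s3y. The Gna11 arrays had pan-leukocyte means of 7.47 to 8.08, and the 3 Gnaq/Gna11 arrays 8.45 to 8.50.

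Each targeted gene had at least 1 probe set that was lower in its knockout arrays than in all others. For Gnaq, 1 of 7 probe sets was at 6.77 ± 0.483 in the 3 Gnaq/Gna11 arrays and 7.63 ± 0.494 in the Gna11 arrays, and its difference from all 9 other arrays was -1.23 (exact permutation p = 0.00455, adjusted p = 0.0191). These 9 pool the Gna11 arrays, at 7.31 to 8.20, with the 6 arrays of the other position number, at 7.76 to 8.56. Against the Gna11 arrays alone the difference was -0.87 (exact permutation p = 0.1, the smallest possible). For Gna11, 1 of 2 probe sets was at 7.22 ± 0.368 in the 6 arrays lacking the gene and 8.33 ± 0.235 in the other 6, a difference of -1.11 (exact permutation p = 0.00217, adjusted p = 0.0191). For Gna12, 2 of 5 probe sets were lower by smaller amounts, -0.32 and -0.31 (adjusted exact permutation p = 0.0191 for both, 6 arrays against 6). The first of them read 3.23 ± 0.106 against 3.54 ± 0.155, under the median of every array, where values carry little information, and the second 5.77 ± 0.114 against 6.07 ± 0.107. The brightest Gna12 probe set was at a value 0.28 above the other arrays without passing (adjusted exact permutation p = 0.0682). For Gna11 and Gna12 these 6 arrays against 6 also differ in the number of the position code. The first principal component separates the same arrays, so passing is a weak check of the label for these genes. For Gna13, 1 of 7 probe sets was at 7.18 ± 0.875 in the 3 Gna12/Gna13 arrays and 8.22 ± 0.271 in the other 9, a difference of -1.04 (exact permutation p = 0.00455, adjusted p = 0.0191). Replicates 1, 2 and 3 of the Gna12/Gna13 arrays read 6.17, 7.61 and 7.76, and the lowest of the other 9 read 7.97. Replicate 1 thus weighed most in this difference. The other 9 arrays again pool both position numbers. Against the Gna12 arrays alone the difference was -1.19 (exact permutation p = 0.1, the smallest possible).

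The remaining probe sets of the targeted genes did not pass. Against the single knockout alone, all 7 Gna13 probe sets were lower in Gna12/Gna13 cells, with a median difference of -0.45, while 3 of 7 Gnaq probe sets were lower in Gnaq/Gna11 cells, with a median difference of 0.04. The second Gna11 probe set, which represents the gene elsewhere, read 9.66 in replicate 2 of the Gna11 cells and 6.86 to 8.29 in the other 11 arrays. Which probe sets lie in the deleted parts of the genes is not given in the sources used here, and a probe set outside them checks nothing. No probe set that passed went against a label.

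**Figure D2:**
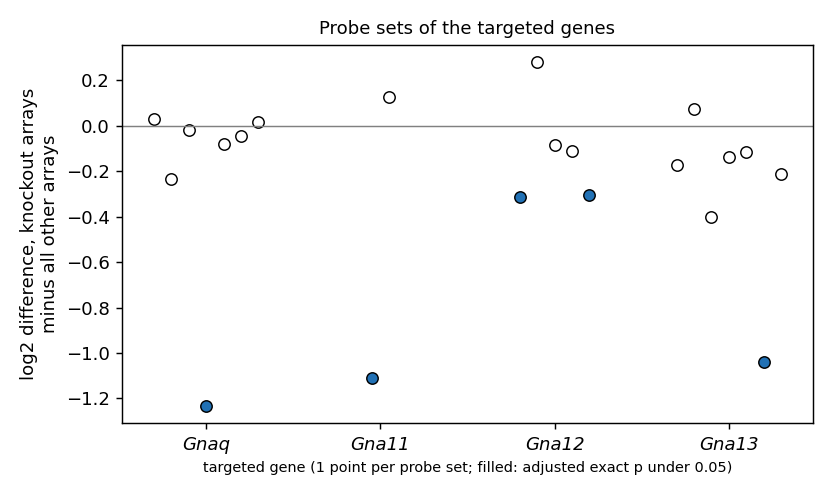
Log2 difference of each probe set of Gnaq, Gna11, Gna12 and Gna13 between the arrays lacking the gene and all other arrays, with 1 point per probe set, filled where the adjusted exact permutation p was under 0.05. The lowest points are Gnaq at -1.23, Gna11 at -1.11 and Gna13 at -1.04, and the filled Gna12 points lie at -0.32 and -0.31.

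Loss of Gnaq in addition to Gna11 was examined by comparing Gnaq/Gna11 with Gna11 cells. Genes of antigen presentation, the interferon response and macrophages were among those that rose, and enzyme genes such as Pon1, Fmo2 and Ces1g were among those that fell. Ccl17, which attracts T cells bearing the receptor Ccr4, rose from 10.9 ± 0.306 to 13.2 ± 0.0440, a difference of 2.23 ± 0.158 (SE, 4.68-fold, adjusted p = 0.000332). The detoxifying esterase Pon1 fell from 11.2 ± 0.156 to 9.04 ± 0.189, a difference of -2.11 ± 0.195 (SE, adjusted p = 0.00132). In all, limma called 335 of 18193 genes, of which 212 were higher and 123 lower in Gnaq/Gna11 cells, and 226 differed at least 2-fold. At an unadjusted p under 0.05 there were 2941 genes, and 19.7% of all genes had arrays of the groups that did not overlap, where chance gives 10%.

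Of the genes named by their size, Npy had the largest rise. Npy, which encodes neuropeptide Y, rose by 6.45 ± 1.02 (SE, adjusted p = 0.0143), from 5.45 ± 0.420 to 11.9 ± 0.0688. Rnase2a, of the eosinophil-associated ribonucleases, rose by 6.16 ± 0.799, the immunoglobulin heavy chain gene Ighm by 4.64 ± 0.879 and Fscn1, an actin-bundling protein abundant in mature dendritic cells, by 4.40 ± 0.828. The monocyte chemokine gene Ccl8 rose by 3.89 ± 0.637, Gdf3 by 3.62 ± 0.802, the macrophage gene Aif1 by 3.56 ± 0.583, the goblet cell gene Clca1 by 3.47 ± 0.470, the metalloproteinase inhibitor gene Timp1 by 3.46 ± 0.465 and Gpnmb by 3.35 ± 0.588. The adjusted p-values of these 10 genes ran from 0.00685 for Rnase2a to 0.0477 for Gdf3.

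The largest fall was that of Ces1g. This carboxylesterase gene was lower by -3.65 ± 0.592 (SE, adjusted p = 0.0157), the fatty acid binding protein gene Fabp1 by -2.53 ± 0.485, the collagen gene Col23a1 by -2.28 ± 0.408 and the transporter gene Slc6a13 by -2.24 ± 0.452. Besides Pon1, the transcription factor gene Nfe2l3 was lower by -2.08 ± 0.404, the lung flavin monooxygenase gene Fmo2 by -2.02 ± 0.227, Dzank1 by -2.01 ± 0.421, the granzyme gene Gzmc by -2.00 ± 0.438 and Phf21a by -1.99 ± 0.285. Their adjusted p-values ran from 0.00132 for Pon1 to 0.0456 for Gzmc.

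**Figure D3:**
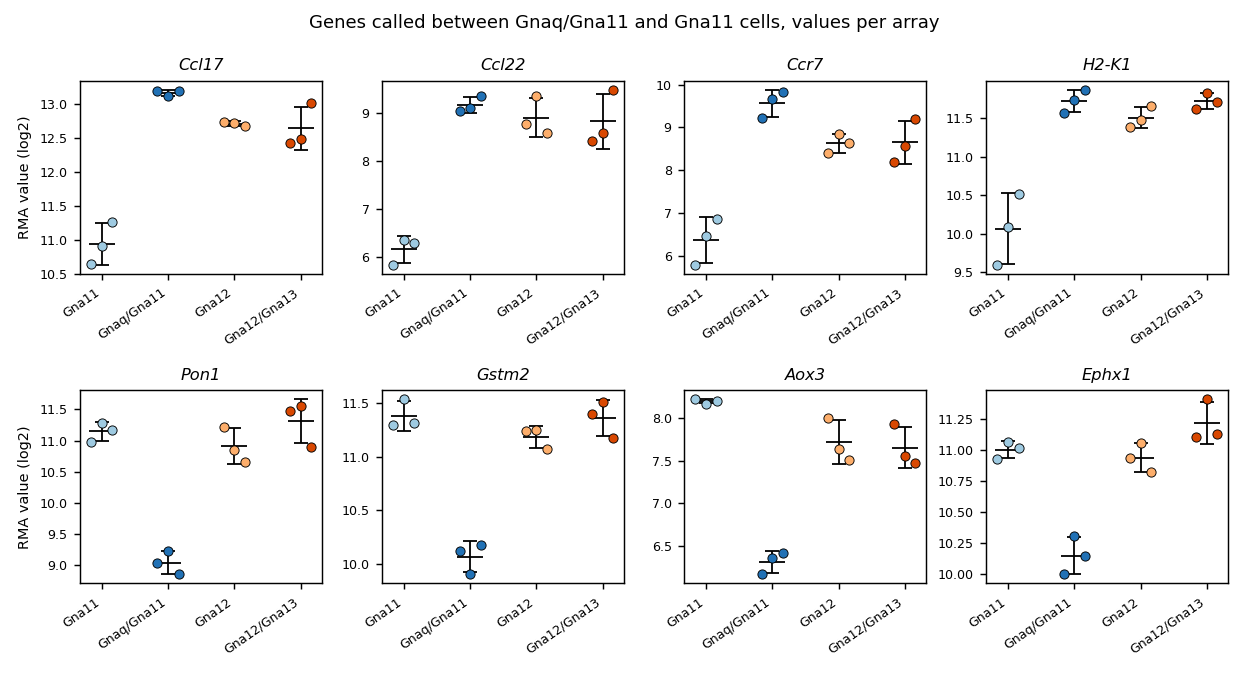
RMA values on the log2 scale of 8 genes called between Gnaq/Gna11 and Gna11 cells, in the 12 arrays (points), with bars for the group mean ± SD (n = 3). By group mean, Ccl17, Ccl22, Ccr7 and H2-K1 were lowest in the Gna11 arrays, and Pon1, Gstm2, Aox3 and Ephx1 were lowest in the Gnaq/Gna11 arrays.

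Of the 32 gene lists, camera called 12 between Gnaq/Gna11 and Gna11 cells, 10 higher and 2 lower, and none of the 12 with an estimated correlation, where the smallest adjusted p was 0.139. Fry called 7 of the lists in 1 direction. Among 14 antigen presentation genes 8 rose, 0 fell and 6 did not pass, with a median difference of 1.17 (camera adjusted p = 3.38e-13, adjusted p = 0.139 with an estimated correlation), or 0.76 with the mean of the probe sets of a gene, and adjusted over the list alone 13 rose. The class I gene H2-K1 rose by 1.66 ± 0.186 (SE), the immunoproteasome gene Psmb8 by 1.57 ± 0.234 and the class II peptide loading gene H2-DMa by 1.54 ± 0.232. Among 21 interferon response genes 4 rose and 17 did not pass, with a median of 0.67 (camera adjusted p = 6.41e-07, adjusted p = 0.308 with an estimated correlation), and 8 rose adjusted over the list alone. The antiviral genes were Oas1a at 1.81 ± 0.237, Oasl1 at 1.71 ± 0.344, Mx1 at 1.48 ± 0.246 and Rsad2 at 0.98 ± 0.157. The mean over the interferon genes was 7.91 in Gnaq/Gna11 replicate 1, 8.77 and 8.44 in replicates 2 and 3, and 7.88 or lower in the Gna11 arrays.

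Among 17 macrophage and monocyte markers 4 rose and 13 did not pass, with a median of 0.95 (camera adjusted p = 6.41e-07, adjusted p = 0.308 with an estimated correlation), and 10 rose adjusted over the list alone. Their median was 0.20 with the pan-leukocyte mean as a covariate (adjusted p = 0.0374) and 0.63 without Gna11 replicate 1. The complement genes C1qc and C1qb rose by 3.22 ± 0.680 (SE) and 1.79 ± 0.373, Adgre1 by 1.88 ± 0.402 and the lysosomal gene Cd68 by 1.63 ± 0.346. Of 23 cytokine and chemokine genes of epithelium, Ccl17 alone rose (median 0.07, camera adjusted p = 0.0311, adjusted p = 0.308 with an estimated correlation), and 5 rose adjusted over the list alone. This list was not called without Gna11 replicate 1 or 3 or Gnaq/Gna11 replicate 1 (camera adjusted p = 0.0816, 0.0708 and 0.166), nor with Eif2s3y or the pan-leukocyte mean as a covariate (0.0900 and 0.445), and its median ran from 0.00 to 0.53 over 14 alternatives. Beside these immune groups, 19 of 20 pan-leukocyte genes had a positive difference, with a median of 0.68, and 1 of them, Itgb2, rose by 1.51. The Gapdh 3' minus 5' difference was 3.70 ± 0.295 in Gna11 and 3.14 ± 0.125 in Gnaq/Gna11 cells, and replicate 2 of the Gna11 cells, which stood apart on the second component, had the lowest array weight, 0.489.

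Of 19 metalloproteinase and protease balance genes 6 rose, 1 fell and 12 did not pass, with a median of 0.46 (camera adjusted p = 1.22e-06, adjusted p = 0.146 with an estimated correlation), and adjusted over the list alone 9 rose and 1 fell. With the pan-leukocyte mean as a covariate the median was 0.25. Besides Timp1, the cathepsin gene Ctsk rose by 2.65 ± 0.510 (SE) and the macrophage elastase gene Mmp12 by 2.33 ± 0.336, while the inhibitor gene Timp3 was lower by -1.08 ± 0.227. Of 15 fibroblast markers 2 rose, the collagen genes Col3a1 at 2.10 ± 0.335 and Col1a1 at 1.57 ± 0.262 (median 0.13, camera adjusted p = 0.0311, adjusted p = 0.308 with an estimated correlation), and 4 rose adjusted over the list alone. The fibroblast list passed under 6 of 14 alternatives, with medians of 0.03 to 0.37. It was not called without Gna11 replicate 1 or 2 or Gnaq/Gna11 replicate 1 (camera adjusted p = 0.0523, 0.0694 and 0.159), among genes at or above the median level (0.257) or with the pan-leukocyte mean as a covariate (0.296). The fibronectin gene Fn1 rose by 2.49 ± 0.411, as 1 of 16 basement membrane and adhesion genes, a list that was not called (camera adjusted p = 0.165). The pan-leukocyte mean was 7.73 ± 0.312 in Gna11 and 8.47 ± 0.0256 in Gnaq/Gna11 cells, beside these genes too.

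Of 17 mitotic genes Birc5 rose, by 1.90 ± 0.391 (SE), with a list median of 0.17 (camera adjusted p = 0.00316, adjusted p = 0.308 with an estimated correlation), and 4 rose adjusted over the list alone. None of 17 DNA replication genes passed (median 0.27, camera adjusted p = 0.00737, adjusted p = 0.375 with an estimated correlation), nor any of 15 cholesterol synthesis genes (median 0.17, camera adjusted p = 0.0227, adjusted p = 0.522 with an estimated correlation). Adjusted over the list alone, 2 and 3 of them rose. With the pan-leukocyte mean as a covariate the mitotic and DNA replication lists were not called (camera adjusted p = 0.0701 and 0.813), and the DNA replication median was 0.02, or 0.12 without replicate 2 of either group. Over 14 alternatives the DNA replication median ran from 0.02 to 0.54. The mitotic median was 0.31 without Gna11 replicate 2 and 0.26 without Gnaq/Gna11 replicate 1. The cholesterol list was not called without Gna11 replicate 2 or Gnaq/Gna11 replicate 3 (camera adjusted p = 0.117 and 0.127) or among genes at or above the median level (0.0732), with medians of 0.10 to 0.41 over 14 alternatives. Of 15 genes of the NRF2 oxidative stress response 3 fell, Gpx2 with -0.95 ± 0.191, Gsta4 with -0.66 ± 0.132 and Gstm1 with -0.66 ± 0.129, and the list median was -0.16 (camera adjusted p = 0.0227, adjusted p = 0.308 with an estimated correlation). Adjusted over the list alone 6 fell. The NRF2 list passed under 9 of 14 alternatives, with medians of -0.47 to -0.10. It was not called without Gna11 replicate 3 or Gnaq/Gna11 replicate 2 (camera adjusted p = 0.289 and 0.0690) or with Eif2s3y as a covariate (0.107).

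Among epithelial lists, none of 15 type II alveolar markers passed (median 0.22, camera adjusted p = 0.0311, adjusted p = 0.637 with an estimated correlation) and 1 rose adjusted over the list alone. None of 14 airway markers passed (median -0.19, camera adjusted p = 0.0311, adjusted p = 0.637 with an estimated correlation) and 3 fell adjusted over the list alone. The type II list was not called without Gna11 replicate 1 or 3 or Gnaq/Gna11 replicate 3 (camera adjusted p = 0.0564, 0.148 and 0.104) or among genes at or above the median level (0.0919), with medians of 0.12 to 0.43 over 14 alternatives. The airway list was not called without replicate 2 of Gna11 or of Gnaq/Gna11 cells (camera adjusted p = 0.387 and 0.151) or with the pan-leukocyte mean as a covariate (0.869), with medians of -0.40 to -0.05. Lists of genes downstream of the deleted G proteins were not called. Their medians were -0.06 for 21 serum response factor and actin genes, -0.24 for 18 YAP and TAZ targets, 0.08 for 20 TGF-beta genes, -0.08 for 17 calcium and NFAT genes and -0.20 for 20 immediate early genes, with camera adjusted p-values of 0.900, 0.340, 0.598, 0.690 and 0.153. Of their members the immediate early gene Nr4a1 alone passed, at -1.39 ± 0.249 (SE). In other lists that were not called, the lysophosphatidic acid receptor gene Lpar3 passed at -1.62 ± 0.252, the G protein gene Gnai2 at 0.70 ± 0.129 and the unfolded protein response gene Sdf2l1 at 2.62 ± 0.445.

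The calls moved with single arrays and with 3 measures of the samples. Without Gna11 replicate 1 or 2, 142 or 166 genes were called, and without Gnaq/Gna11 replicate 1, 2 or 3, 221, 102 or 105, while 3 (AA467197, Ccl17 and Gstm2) were called with the Gapdh difference and 13 with the pan-leukocyte mean as a covariate. With Eif2s3y as a covariate 237 were called, 159 of them among the 335. Array quality weights gave 174 and a fit to the 6 arrays compared 139. Of the genes named above, Ccl17 passed under each of 19 alternatives (limma adjusted p from 0.000127 to 0.037) and Pon1 under 18, while Adgre1, Cd68, Gzmc and Dzank1 passed under 6, C1qc under 5 and Gdf3 and Timp3 under 4. Birc5 passed under 6 of 18.

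**Figure D4:**
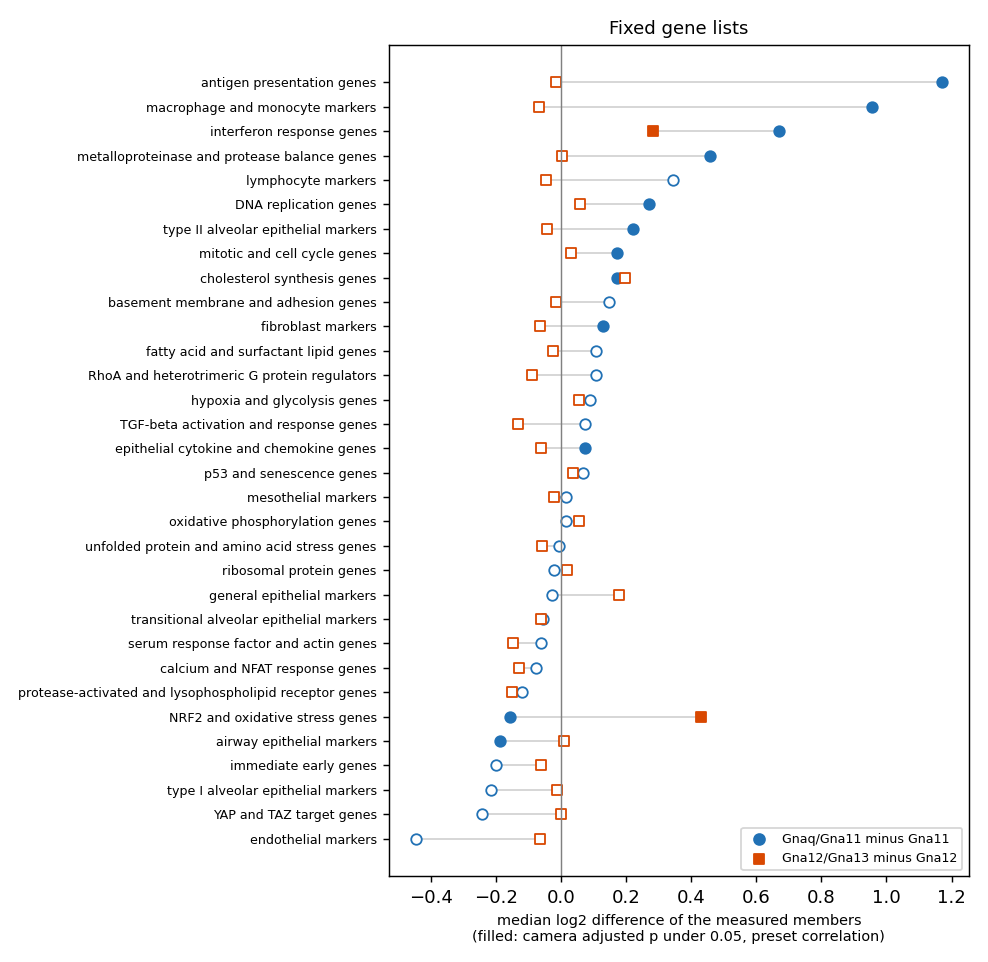
Median log2 difference of the measured members of 32 gene lists, for Gnaq/Gna11 minus Gna11 (circles) and Gna12/Gna13 minus Gna12 (squares), filled where the camera adjusted p at the preset correlation was under 0.05. No list was called with an estimated correlation, the circle farthest to the right is antigen presentation at 1.17, and the filled squares are the NRF2 list at 0.43 and the interferon list at 0.28.

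Loss of Gna13 in addition to Gna12 was examined in the same way. No gene passed between Gna12/Gna13 and Gna12 cells: limma called 0 of 18193 genes, with a smallest adjusted p of 0.128, and 820 genes had an unadjusted p under 0.05. The arrays of the groups did not overlap for 11.3% of the genes, where chance gives 10%. The gene rule gave values that did not pass, the dynein gene Dnah7a at 1.21 ± 0.189 (SE, adjusted p = 0.433), the mitochondrial calcium channel gene Mcu at 0.78 ± 0.130, the carbonyl reductase gene Cbr1 at 0.73 ± 0.141, Wdpcp at 1.23 ± 0.271 and the glutathione transferase gene Gstp1 at 0.30 ± 0.0640. On the negative side were Wdyhv1 at -1.18 ± 0.212 (adjusted p = 0.492), the keratin gene Krt78 at -1.01 ± 0.216, the serine synthesis gene Phgdh at -0.64 ± 0.147, Fam20a at -1.55 ± 0.360 and Myh7 at -1.10 ± 0.295. Zfp324, Uox, Pcbd1, Cibar1 and Cep19 had positive values of 0.50 to 0.98, and Wdr59, Stambp, Cdk16, Clec2l and Il18rap negative values of -1.31 to -0.53, all with adjusted p-values of 0.923 or above.

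Camera called 2 of the 32 lists between Gna12/Gna13 and Gna12 cells, both higher. Of 15 genes of the NRF2 response 0 passed and 14 had a positive difference, with a median of 0.43 (camera adjusted p = 0.000176, adjusted p = 0.317 with an estimated correlation). Nqo1, a quinone reductase, was at 1.03 ± 0.390 (SE), Ugdh at 0.62 ± 0.224 and Gclc, of glutathione synthesis, at 0.56 ± 0.380. Of 21 interferon response genes 0 passed and 18 had a positive difference, with a median of 0.28 (camera adjusted p = 0.00299, adjusted p = 0.690 with an estimated correlation), among them Bst2 at 1.28 ± 0.474, Rtp4 at 0.93 ± 0.450 and Gbp3 at 0.81 ± 0.296. The mean over the interferon genes was 7.96 in Gna12/Gna13 replicate 1, 8.48 and 8.41 in replicates 2 and 3, and 7.94 to 7.95 in the Gna12 arrays. Without Gna12/Gna13 replicate 2 the interferon list was not called (camera adjusted p = 0.0613), and without Gna12 replicate 1 or 2 or Gna12/Gna13 replicate 1 its median was 0.45, 0.18 and 0.44. Adjusted over the list alone, 0 genes of either list passed, and fry called 0 lists in 1 direction and 0 in either direction. The pan-leukocyte genes had a median of -0.33, with 18 of 20 negative, and the Gapdh difference was 3.00 ± 0.298 in Gna12 and 3.15 ± 0.174 in Gna12/Gna13 cells.

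Lists near RhoA signalling were not called between Gna12/Gna13 and Gna12 cells. The median was -0.15 for serum response factor and actin genes (camera adjusted p = 0.145), -0.13 for TGF-beta genes (camera adjusted p = 0.0766) and -0.06 for immediate early genes (camera adjusted p = 0.0581). YAP and TAZ targets divided evenly, with 9 positive and 9 negative (camera adjusted p = 0.618). Antigen presentation genes had 7 positive and 7 negative differences and a median of -0.02 (camera adjusted p = 0.813), and macrophage markers a median of -0.07 (camera adjusted p = 0.268). Without Gna12 replicate 1 limma called 1 gene (Lrmda), without Gna12 replicate 3 it called 3 (H2-Q10, Il1f9 and Stfa2l1), and without Gna12/Gna13 replicate 1 or 2 it called 1 (Slamf8 or 2010109A12Rik), all named after their values were seen. The number of called lists was 9 without Gna12/Gna13 replicate 3, 5 without Gna12 replicate 1 or 2, 4 without Gna12 replicate 3 and 1 without Gna12/Gna13 replicate 2.

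The difference between the double and the single knockout was then compared between the pairs. For 13 genes it differed, 4 being higher and 9 lower in the Gq/11 pair, and 1967 genes had an unadjusted p under 0.05. The chemokine genes Ccl17 and Ccl22 and the chemokine receptor gene Ccr7 were higher in Gnaq/Gna11 than in Gna11 cells by 2.23 ± 0.158, 3.01 ± 0.301 and 3.19 ± 0.321 (SE), against -0.07 ± 0.158, -0.07 ± 0.301 and 0.03 ± 0.321 for Gna12/Gna13 and Gna12 cells. Ccl17 was at 10.9 ± 0.306 in Gna11, 13.2 ± 0.0440 in Gnaq/Gna11, 12.7 ± 0.0369 in Gna12 and 12.6 ± 0.320 in Gna12/Gna13 cells, Ccl22 at 6.15 ± 0.281, 9.16 ± 0.172, 8.90 ± 0.407 and 8.83 ± 0.572 and Ccr7 at 6.37 ± 0.544, 9.56 ± 0.315, 8.63 ± 0.225 and 8.65 ± 0.507, so for these 3 genes the Gna11 arrays stood below the 9 others. The differences between the pairs were 2.30 ± 0.224 for Ccl17 (adjusted p = 0.00886), 3.08 ± 0.426 for Ccl22 (adjusted p = 0.0398) and 3.17 ± 0.453 for Ccr7 (adjusted p = 0.0413). The fourth was AA467197, outside the naming rule, at 3.51 ± 0.424.

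The 9 genes that were lower in the Gq/11 pair included 5 enzymes. The carboxylesterase gene Ces1g had a difference between the pairs of -5.68 ± 0.837 (SE, adjusted p = 0.0423), Pon1 of -2.51 ± 0.276 (adjusted p = 0.0114), the aldehyde oxidase gene Aox3 of -1.82 ± 0.274, the glutathione transferase gene Gstm2 of -1.49 ± 0.166 and the epoxide hydrolase gene Ephx1 of -1.13 ± 0.163. The others were Krtap17-1 at -1.46 ± 0.208, the oxysterol binding protein gene Osbpl6 at -1.21 ± 0.166, Pgrmc1 at -1.19 ± 0.176 and, outside the naming rule, 2310034G01Rik at -0.98 ± 0.125. Kng1, Wfdc17, Fbln2, Ext1, Proz, Ceacam10, Veph1, Gsta2 and Ces1f, which the rule added, did not pass, with adjusted p-values of 0.0564 to 0.0567.

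Camera called 10 lists for the difference between the pairs, and none with an estimated correlation. Antigen presentation genes had a median difference between the pairs of 1.17 (camera adjusted p = 1.27e-11, adjusted p = 0.123 with an estimated correlation), with 0 of 14 passing over all genes and 11 higher adjusted over the list alone. Macrophage markers had 0.91 (camera adjusted p = 1.23e-07, adjusted p = 0.280 with an estimated correlation), with 0 of 17 passing and 9 higher adjusted over the list alone, and were not called with the pan-leukocyte mean as a covariate (median 0.10, camera adjusted p = 0.658), where the antigen presentation median was 0.77. The NRF2 list had -0.63 (camera adjusted p = 1.41e-05, adjusted p = 0.123 with an estimated correlation), with 0 of 15 passing and 6 lower adjusted over the list alone. By median, the rise of this list in the G12/13 pair was larger than its fall in the Gq/11 pair. The pan-leukocyte genes had a median of 1.09 for the difference between the pairs. The count of 13 genes became 4, 22 or 24 without Gna11 replicate 1, 2 or 3, 40 or 8 without Gnaq/Gna11 replicate 1 or 3, 6 or 0 without Gna12 replicate 1 or 2 (1755 genes at an unadjusted p under 0.05 for the latter) and 7, 4 or 28 without Gna12/Gna13 replicate 1, 2 or 3, and the lists 6 without Gnaq/Gna11 replicate 3 and 5 without Gna12 replicate 3. With the Gapdh difference as a covariate limma called 0 (1483 at an unadjusted p under 0.05), and with the pan-leukocyte mean 1 (Meg3, which was not among the 13).

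Across genes, which are not independent replicates, the differences of the pairs had a Pearson's r of -0.03 and a Spearman's rho of -0.00182 over 18193 genes. Of the 335 genes called between the Gq/11 groups, 48.4% had the same sign between Gna12/Gna13 and Gna12 cells. Without Gna12/Gna13 replicate 1, r was 0.119.

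For the single knockouts, the number in the position code of the labels differs with genotype, so the effects of genotype and code cannot be told apart. Between Gna12 and Gna11 cells limma called 513 genes, 316 higher and 197 lower in Gna12 cells, 304 of them at least 2-fold, and 3795 genes had an unadjusted p under 0.05. The arrays did not overlap for 26.3% of the genes, where chance gives 10%. The histidine-degrading enzyme gene Hal was at 9.11 ± 0.490 in Gna11 and 4.78 ± 0.428 in Gna12 cells, a difference of -4.33 ± 0.304 (SE, adjusted p = 0.000295), and the integrin gene Itga9 at 10.7 ± 0.260 and 6.52 ± 0.168, a difference of -4.21 ± 0.361 (adjusted p = 0.000609). Hal was at 10.4 ± 0.339 in Gnaq/Gna11 and 4.83 ± 0.265 in Gna12/Gna13 cells.

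Further genes lower in Gna12 cells were the kallikrein gene Klk1 at -3.27 ± 0.396 (SE, adjusted p = 0.00461), the mast cell chymase gene Cma1 at -2.68 ± 0.637, Elobl, Tesc, Hsd3b2, Tshb, Hyi and Adat2, from -2.71 for Elobl to -2.47 for Adat2. The largest rises were Ighm at 5.04 ± 0.879, Ceacam10 at 4.18 ± 0.359, the apolipoprotein gene Apoc2 at 4.02 ± 0.668, Clec1b at 3.98 ± 0.900, the cystine transporter gene Slc7a11 at 3.55 ± 0.643 and Lbhd2 at 3.52 ± 0.445. The hepcidin gene Hamp rose by 3.16 ± 0.687, the cytokine gene Il10 by 3.14 ± 0.466, Zeb2 by 3.12 ± 0.502 and the neutrophil and monocyte gene S100a9 by 3.11 ± 0.704. Their adjusted p-values ran from 0.000609 for Ceacam10 to 0.0424 for S100a9.

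Camera called 8 lists between the single knockouts, 7 higher and 1 lower in Gna12 cells, and none with an estimated correlation, where the smallest adjusted p was 0.269, while fry called 6. Of 17 macrophage and monocyte markers 4 rose and 13 did not pass, with a median of 1.32 (camera adjusted p = 1.03e-09, adjusted p = 0.269 with an estimated correlation), and 13 rose adjusted over the list alone. Cd14 rose by 1.71 ± 0.395 (SE), Cd68 by 1.47 ± 0.346, Ctss by 1.11 ± 0.255 and Laptm5 by 0.99 ± 0.217. Of 14 antigen presentation genes 5 rose and 9 did not pass, with a median of 0.53 (camera adjusted p = 3.07e-05, adjusted p = 0.269 with an estimated correlation), led by H2-DMa at 1.60 ± 0.232, and adjusted over the list alone 7 rose and 1 fell. With the pan-leukocyte mean as a covariate neither list was called, with medians of -0.05 and 0.19 (camera adjusted p = 0.918 and 0.155). All 20 pan-leukocyte genes were higher in Gna12 cells by value, with a median of 1.39, and 8 rose. The Gapdh difference was 3.70 ± 0.295 in Gna11 and 3.00 ± 0.298 in Gna12 cells.

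Of 15 type II alveolar markers 2 fell, Il33 with -1.95 ± 0.458 (SE) and the phosphate transporter gene Slc34a2 with -0.85 ± 0.200, and 13 did not pass, with a median of -0.38 (camera adjusted p = 0.00261, adjusted p = 0.493 with an estimated correlation). Of 14 markers of transitional alveolar cells 2 rose, the cell cycle inhibitor gene Cdkn1a by 1.16 ± 0.247 and Clu by 0.20 ± 0.0444, with a median of 0.18 (camera adjusted p = 0.00262, adjusted p = 0.269 with an estimated correlation). Adjusted over the list alone, 4 type II markers fell and 5 transitional markers rose. The type II median was -0.24 without Gna12 replicate 2, and the transitional median 0.10 without Gna11 replicate 2. The transitional list was not called among genes at or above the median level (camera adjusted p = 0.0729). Of 19 metalloproteinase and protease balance genes 2 rose, Ctsk by 2.55 ± 0.510 and Ctsb by 0.20 ± 0.0368 (median 0.25, camera adjusted p = 0.000126, adjusted p = 0.269 with an estimated correlation), and 8 rose adjusted over the list alone. Ctsb passed under 10 of 18 alternatives, with differences of 0.09 to 1.55. The protease list median ran from 0.20 to 0.54 over 14 alternatives. Of 23 cytokine and chemokine genes 2 rose and 1 fell, Cxcl2 by 1.86 ± 0.258, Ccl17 by 1.77 ± 0.158 and Il33 (median 0.14, camera adjusted p = 0.0378, adjusted p = 0.269 with an estimated correlation), with the same counts adjusted over the list alone. The cytokine list passed under 7 of 14 alternatives, with medians of -0.06 to 0.53. It was not called without Gna11 replicate 1 or 3 or Gna12 replicate 1 (camera adjusted p = 0.0610, 0.0555 and 0.0627) or with Eif2s3y as a covariate (0.0516). With the pan-leukocyte mean as a covariate none of the type II, transitional, protease and cytokine lists was called (camera adjusted p = 0.918, 0.0912, 0.289 and 0.653).

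Of 21 interferon response genes 2 rose between the single knockouts, Mx1 by 1.72 ± 0.246 (SE) and Rsad2 by 1.04 ± 0.157 (median 0.03, camera adjusted p = 0.0369, adjusted p = 0.528 with an estimated correlation), and 4 rose adjusted over the list alone. The interferon list passed under 5 of 14 alternatives, with medians of -0.17 to 0.12, and was not called without Gna11 replicate 2 or 3 or Gna12 replicate 1 or 3 (camera adjusted p = 0.163, 0.0566, 0.0510 and 0.0531), with the mean of the probe sets of a gene (0.0942) or among genes at or above the median level (0.158). None of 21 serum response factor and actin genes passed (median 0.20, camera adjusted p = 0.0352, adjusted p = 0.269 with an estimated correlation), and 2 rose adjusted over the list alone. This list was not called without Gna11 replicate 2 (median 0.13, camera adjusted p = 0.117) or Gna12 replicate 1 (0.120) or among genes at or above the median level (0.117), and neither list with the pan-leukocyte mean as a covariate (0.789 and 0.168). Single genes of other lists that rose included Cd44 by 2.31 ± 0.298, Fn1 by 2.10 ± 0.411, the RhoA exchange factor gene Arhgef11 by 1.87 ± 0.422, Sdf2l1 by 2.08 ± 0.445, Nr4a3 by 0.96 ± 0.183, the glycolysis gene Pfkp by 0.73 ± 0.146, Gnai2 by 0.96 ± 0.129 and Gclm by 0.84 ± 0.195, and the lipid synthesis gene Gpam was lower by -1.37 ± 0.163. Without Gna11 replicate 1 or 2, 210 or 232 genes were called between the single knockouts, and without Gna12 replicate 1 or 2, 139 or 62. With only the 6 arrays of these groups in the fit 22 were called, and with the Gapdh difference or the pan-leukocyte mean as a covariate limma called 0 (1387 or 1029 at an unadjusted p under 0.05). With these covariates the median absolute difference of the 513 genes went from 1.14 (SE 0.218) to 0.86 (SE 0.337) and 0.69 (SE 0.396), with 513 and 505 signs kept, so differences were smaller and errors larger. Of the lists, 13 were called without Gna11 replicate 3 or without Gna12 replicate 2, and 2 with the pan-leukocyte mean as a covariate.

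The comparisons of Gnaq/Gna11 and of Gna12 cells with Gna11 cells share the 3 Gna11 arrays. Together 54 genes, among them Ccl17, H2-K1 and Fn1, were called higher in both, where independent lists of these sizes would share 3.68, and 15 were called lower in both, where 1.33 would be shared. The differences correlated across genes with r = 0.478 and a covariance of 0.112. In 50 simulations of unchanged groups with shared controls the mean r was 0.5, the mean covariance 0.0429, and 0 genes were called by limma in both. The genes were simulated independently and without change, so hardly any could be called, and the 0 is no measure for the overlap. Shifts of a whole control array that many genes share were not simulated. The 3 control arrays are too few to split, so part or all of the overlap may come from the shared controls.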

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

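The tests of leukocyte RNA, of the spread within groups and of the Gna13 transcript, the added gene lists, the covariates and the grouping of the splits by the Gq/11 groups were chosen only after the result was seen. The difference between double and single knockout was tested for a difference between the pairs, and 13 genes passed: Ccl17 at 2.298, AA467197 at 3.506, Ccr7 at 3.167, Ccl22 at 3.081, Ces1g at -5.676, Pon1 at -2.507, Aox3 at -1.82, Gstm2 at -1.49, Krtap17-1 at -1.455, Osbpl6 at -1.21, Pgrmc1 at -1.194, Ephx1 at -1.131 and 2310034G01Rik at -0.9804 (log2, limma). Of 10 lists that passed with camera at the preset correlation, antigen presentation genes had a median of 1.175, macrophage and monocyte markers 0.9078, metalloproteinase and protease balance genes 0.5646, interferon response genes 0.3918, cytokine and chemokine genes 0.3247, fibroblast markers 0.2055, type II alveolar markers 0.1353, mitotic genes 0.129, airway markers -0.1496 and NRF2 genes -0.6267. With an estimated correlation 0 of the 10 passed. The interferon list was not called without Gna11 replicate 2, Gnaq/Gna11 replicate 2 or 3, Gna12 replicate 3 or Gna12/Gna13 replicate 1 (camera adjusted p = 0.102, 0.167, 0.0793, 0.0504 and 0.267), the cytokine list without Gnaq/Gna11 replicate 1 (0.0572), and the fibroblast list without that array or Gna12 replicate 3 (0.0686 and 0.0504). The type II list was not called without Gna11 replicate 1 or 3, Gnaq/Gna11 replicate 3, Gna12 replicate 3 or Gna12/Gna13 replicate 2 (0.0545, 0.102, 0.0927, 0.257 and 0.140), and the mitotic list without Gnaq/Gna11 replicate 3, Gna12 replicate 3 or Gna12/Gna13 replicate 1 (0.0639, 0.0504 and 0.0908). The airway list was not called without Gna11 replicate 2, Gnaq/Gna11 replicate 2 or 3, Gna12 replicate 1 or 3, or Gna12/Gna13 replicate 1 or 2 (0.318, 0.138, 0.0726, 0.110, 0.133, 0.267 and 0.0605). With the pan-leukocyte mean as a covariate the macrophage, interferon, cytokine, fibroblast, mitotic and airway lists were not called (0.658, 0.576, 0.322, 0.322, 0.513 and 0.994), and the medians of the interferon and airway lists were -0.0246 and 0.0130. Among genes at or above the median level the fibroblast, type II and airway lists were not called (0.0544, 0.0711 and 0.0535), nor was the mitotic list with Eif2s3y as a covariate (0.0819). Over 20 alternatives, 19 for the mitotic list, the medians ran from 0.10 to 0.77 for the cytokine, 0.13 to 0.65 for the fibroblast, 0.10 to 0.56 for the type II and 0.08 to 0.26 for the mitotic list. The protease median was 0.358 without Gna12/Gna13 replicate 1.

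The first pattern is the 335 genes called between Gnaq/Gna11 and Gna11 cells. Slopes within the 6 Gna12 and Gna12/Gna13 arrays, times the difference between the Gq/11 groups, gave a median share of the observed difference of 0.0116 for sex, from the Y-linked gene Eif2s3y (-0.0266 to 0.0483 with each array left out), 0.0533 for RNA quality, from the Gapdh probe sets (-0.0383 to 0.251), and 0.105 for the amount of leukocyte RNA (-0.0864 to 0.227). The slopes rest on 6 arrays of other genotypes, and the genes were picked for their differences between the Gq/11 groups, which lowers the share. Of these 6 arrays only the 2 of replicate 2 had low Eif2s3y, so the slope for sex cannot be told apart from the replicate number. The sex-linked gene Xist was at 6.54 and 6.72 in these 2 arrays. In the Gnaq/Gna11 arrays it was at 7.29 to 9.31, although Eif2s3y was low in all of them. The shares were low, but they do not decide how much each measure contributes, and each stays possible. With Eif2s3y, the Gapdh difference or the leukocyte mean as a covariate 159, 3 and 13 of the 335 genes were still called: the median absolute difference went from 1.32 (SE 0.234) to 1.33 (SE 0.261), 1.22 (SE 0.333) and 1.11 (SE 0.306), with all 335 signs kept, so the calls ended more through a larger error than through a smaller difference. Loss of Gnaq stays open as an untested biological explanation, the position letter is confounded with it, and the sharing of calls with the Gna12 arrays leaves a property of the Gna11 arrays open too.

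The second pattern is the rise of antigen presentation, macrophage and interferon lists in Gnaq/Gna11 cells. More leukocytes of every kind may be a source: the pan-leukocyte genes had a median of 0.679 (95% bootstrap interval 0.443 to 0.94), on both sides of 0.586, the level set for this test from the antigen presentation list. The bootstrap resampled genes, not arrays, so its intervals hold no spread between arrays, and 0.586 itself comes from the same arrays. Their most abundant members were Laptm5, at 10.87 in Gna11 and 11.6 in Gnaq/Gna11 cells, and Plek, at 10.09 and 10.19. More dendritic cells may be another, with a median of 0.321 (0.17 to 0.594) for 18 genes that left out Ccl17, Ccl22 and Ccr7, so both stay open, as does an effect of Gnaq loss on the epithelial cells. Of the measured genes 2 of 20 pan-leukocyte, 4 of 17 macrophage and 0 of 14 antigen presentation genes stand in another list, and 18, 16 and 14 were at or above the median level in Gna11 cells. For the 18 dendritic cell genes these counts were 0 and 11. A larger share of that list thus lay under the median level, where values carry little information.

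The third pattern is that limma called 0 genes between Gna12/Gna13 and Gna12 cells, with 820 at an unadjusted p under 0.05. The median SD within groups was 0.193 in the G12/13 pair and 0.223 in the Gq/11 pair, a ratio of 0.865, so it was not larger. All 12 arrays shared 1 estimate of the spread per gene, and the median SE was 0.192 for both pairs. The spread of this pair alone therefore did not set its test, and the ratio does not bear on the 0 calls. On simulated data 54% of genes changed by 1 on the log2 scale were called in this comparison. An incomplete loss of the Gna13 transcript may contribute: its 7 probe sets differed by a median of -0.454 (-1.19 to -0.141), but whether they lie in the deleted part is not given in the sources used here, and a small effect of Gna13 loss stays open as untested.

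Other splits of the arrays bear on these counts. In each comparison of 2 groups the 10 splits are too few for a share under 0.05. Each other split mixes the 2 groups, so a real difference would add to the spread within groups and lower the counts. A gap between the real and the other gene counts therefore does not measure chance. For Gnaq/Gna11 against Gna11, 1 split gave as many genes as the real 335, the real one, and the highest other gave 2, while 1 gave as many lists as the real 12 and the highest other gave 6. For Gna12/Gna13 against Gna12, 10 splits gave at least the real 0 genes (highest other 1) and 8 at least the real 2 lists (highest other 9). For Gna12 against Gna11, 1 split gave as many as the real 513 genes (highest other 2) and 3 as many as the real 8 lists (highest other 15).

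For the difference between the pairs, 7 of 100 splits gave at least the real 13 genes, and the highest other gave 164. The 6 others among these 7 all kept the real Gq/11 groups and so hold their difference, while the 88 splits that broke these groups gave 0 to 2 genes, with that difference then adding to the spread within groups. The number of splits therefore does not measure chance for the 13 genes, in either direction. For the lists 9 of 100 splits gave at least the real 10 (highest other 12), 5 of them among the 88, so chance is not excluded for the lists. A correlation between the pairs as large in size as 0.0291 came from 87 of 100 splits (highest other 0.22).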

How the results depend on the processing

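The covariates and the fit without 2 Gna11 arrays were chosen after the data were seen. Of the values of called or named genes under alternatives other than leaving out an array, 413 of 606 for Gnaq/Gna11 against Gna11 and 369 of 560 for Gna12 against Gna11 kept direction and side of the threshold, 193 and 189 kept only the direction, and 0 and 2 reversed. For Gna12/Gna13 against Gna12, 234 of 234 stayed not passed. For the difference between the pairs, 167 of 238 stayed, 38 no longer passed and 33 newly passed. With an array left out, fewer of the calls held. For Gnaq/Gna11 against Gna11 154 of 282 values stayed and 128 kept only the direction, and for Gna12 against Gna11 155 of 282 and 127. Between the pairs 157 of 240 stayed, 72 no longer passed and 11 newly passed, and for Gna12/Gna13 against Gna12 120 of 120 stayed not passed. The cause was not tested except where fewer genes, fewer arrays or another threshold is the setting itself. Arrays give no depth, and values near background carry little information.

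For Gnaq/Gna11 against Gna11 (335 genes) an adjusted p under 0.1 gave 689, array weights 174, only the arrays compared 139, the Eif2s3y covariate 237, the Gapdh covariate 3, the pan-leukocyte covariate 13 and the fit without the 2 Gna11 arrays with high Eif2s3y 679. That fit leaves Gna11 replicate 2 alone, assumed to vary like the others, although its array weight was the lowest (0.489) and its second component score the highest (50.9), so the 679 say little about sex. With the mean of the probe sets Fscn1 went from 4.40 to 1.44 in this comparison, and between the single knockouts Ighm went from 5.04 to 1.67, Itga9 from -4.21 to -1.32, Ctsb from 0.20 to 0.99 and Pfkp from 0.73 to 0.16. Over 19 alternatives for Gnaq/Gna11 against Gna11, Phf21a ran from -2.34 to -0.67 and Psmb8 from 0.86 to 1.79. Leaving out each array gave 102 to 375. For Gna12/Gna13 against Gna12 (0 genes with limma, 820 at an unadjusted p under 0.05) leaving out each array gave 0 to 3.

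Between the pairs (13 genes) an adjusted p under 0.1 gave 89, the mean of the probe sets 35, genes at or above the median level 42, quantile normalization 23, no intensity trend 22, array weights 28, the Gapdh covariate 0 (1483 at an unadjusted p under 0.05), the pan-leukocyte covariate 1, and leaving out each array 0 to 40. For Gna12 against Gna11 (513 genes) a 2-fold minimum gave 304, an adjusted p under 0.1 1348, genes at or above the median level 798, only the arrays compared 22, and the Gapdh and pan-leukocyte covariates 0 and 0 (1387 and 1029 at an unadjusted p under 0.05). Leaving out each array gave 62 to 736.

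With the pan-leukocyte covariate Gnaq went from -0.19 to 0.0396 between the Gq/11 groups, and between the single knockouts Cd14 went to -0.25, Cd68 to -0.0779 and the median of the macrophage markers to -0.0458, while the airway markers went to 0.0130 for the difference between the pairs. Between the single knockouts Gna11 went from -0.70 to 0.12 with the mean of its probe sets and 0.95 with its probe set of smallest p, and Gna12 from 0.30 to -0.12 and -0.33, because these settings use other probe sets.

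Of the 32 lists, an estimated correlation called 0 in each comparison. For Gnaq/Gna11 against Gna11 (12 lists) fry called 7 and its mixed form 22, and leaving out each array gave 9 to 12. For Gna12/Gna13 against Gna12 (2 lists) fry called 0 and 0, the mean of the probe sets 4, genes at or above the median level 4, the Eif2s3y covariate 4, and leaving out each array gave 1 to 9. Between the pairs (10 lists) fry called 4, genes at or above the median level 6, the pan-leukocyte covariate 6, and leaving out each array 5 to 13. For Gna12 against Gna11 (8 lists) fry in its mixed form called 24, the pan-leukocyte covariate 2, and leaving out each array 6 to 13. The correlation of the pairs, -0.03, was 0.119 without Gna12/Gna13 replicate 1, with a range of -0.107 to 0.119.

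The replicate numbers were not treated as pairs because not every correlation of same-numbered arrays was over 0.1. They were 0.01, 0.00 and 0.06 in the Gq/11 pair, -0.03, 0.34 and 0.18 in the G12/13 pair and 0.03, 0.21 and 0.14 between the single knockouts, and 3, 4 and 4 of 6 arrays correlated best with their own number. Since Eif2s3y followed the number in 3 of 4 groups, a shared source of same-numbered arrays is not excluded. With the replicate block 309, 0 (908 at an unadjusted p under 0.05 with limma), 16 and 445 genes and 10, 2, 11 and 9 lists were called in the order above, and the correlation of the pairs was -0.0291. The NRF2 and fibroblast lists of the Gq/11 pair and the cytokine list of the single knockouts were then not called (camera adjusted p = 0.0519, 0.0519 and 0.0555).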

Other observations

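The list of xenobiotic and aldehyde metabolism families, the other added cell type lists and the place of the G12/13 arrays among the called genes were chosen only after the result was seen. Of 168 measured genes of xenobiotic and aldehyde metabolism families 18 fell and 1 rose between Gnaq/Gna11 and Gna11 cells, where 1.14 falls are expected from the number of calls (Fisher's exact p = 7.19e-17, which treats genes as independent). Besides Ces1g, Pon1 and Fmo2, the genes that fell were Aox3 (-1.88), the carboxylesterase gene Ces1f (-1.85), the glutathione transferase genes Gstm3 (-1.51), Gsta2 (-1.37), Gstm2 (-1.31), Gsta4, Gstm1 and Gstk1 (-0.37), the cytochrome P450 genes Cyp3a13 (-1.20), Cyp4b1 (-0.93) and Cyp2b10 (-0.37), Fmo5, Ephx1 (-0.85), Aldh2 (-0.33) and Aldh1a7 (-0.24), and Akr1b8 rose (1.63). The families were chosen because called genes belonged to them, so the enrichment is not independent evidence. Among the 9 genes lower in the Gq/11 pair in the difference between the pairs, 5 belong to them, where 0.0831 are expected (Fisher's exact p = 7.74e-09).

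Of 18 dendritic cell genes Fscn1 rose in Gnaq/Gna11 over Gna11 cells, and Cd86 and Marcks rose in Gna12 over Gna11 cells. Of 12 genes of alternatively activated macrophages 0 passed with limma, with a median of 0.31 in Gnaq/Gna11 against Gna11 cells. Of 13 eosinophil and mast cell genes 0 passed there, with a median of -0.08, and the mast cell protease genes Cma1 (-2.68) and Mcpt4 (-0.36) were lower in Gna12 than in Gna11 cells. Only 2 of these 13 genes were at or above the median level in Gna11 cells, so the list says little about such cells.

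Of the 212 genes called higher in Gnaq/Gna11 than in Gna11 cells, the mean of the G12/13 arrays lay nearer Gna11 for 117 and nearer Gnaq/Gna11 for 95, at a median of 41.7% of the difference. Of the 123 called lower it lay nearer Gna11 for 79 and nearer Gnaq/Gna11 for 44, at a median of 32.1%.

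DNA of the original strain carried along with the targeted Gnaq locus was examined as a hypothesis. Of the 335 called genes 0.896%, or 3 of the 100 measured genes nearest Gnaq (Aldh1a7, Ms4a6d and Ms4a7), lay beside it, where 1.85 are expected (Fisher's exact p = 0.435). Calls were thus not clearly in excess among these 100 genes. At most 100 of the 335 calls could lie there, and DNA farther from Gnaq was not examined. The count therefore cannot tell whether carried DNA is a source of most calls.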
